A study of Oryza sativa with 7 samples.

How the data were processed

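Messenger RNA was sequenced from whole caryopses of field-grown rice (Oryza sativa, cultivar Kitaake) collected 2 days after fertilization. The labels list 7 libraries: 3 of the wild type (WT) and 2 of each of the independent mutant alleles osbzip76-1 and osbzip76-2. Per the labels' protocols, poly(A) RNA was selected with poly-T beads and libraries were made with a NEBNext Ultra kit, and the replicates were biological. The authors deposited one table of RPKM values, in which reads are scaled by gene model length and by a library total, with a column per library and a mean column per genotype class. Its 35825 rows were not filtered by any step that the file headers record. The genome build was IRGSP-1.0, per the submitters' processing notes. The aligner, the read counter, its use of strand and the annotation release are not given in the sources used here. Paralogs, overlapping genes and antisense partners can therefore share reads, and near-identical families such as the glutelins are uncertain gene by gene.

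Columns were matched to libraries by name. The table used here had a column for 6 of the libraries, and replicate 1 of osbzip76-2 was not analysed here. The osbzip76-2 group was thus 1 library, so each of its comparisons assumed that this library varied like those of the other groups. The test plan, fixed for 7 libraries before the data were examined, was otherwise kept. The authors' mean columns equalled the means of the 3 WT and the 3 mutant library columns within rounding and were used only for that check.

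RPKM values are not counts, but their low values rise in steps of 1 read. The total behind each library was recovered as the number that makes all of its values whole numbers of reads, given 1 length per gene. Of the 168975 values above 0, 99.99% came out whole within 0.02 reads. The recovered totals were 24093618, 22504199 and 24887952 reads for WT replicates 1 to 3, 19900850 and 21107973 reads for osbzip76-1 replicates 1 and 2, and 23646074 reads for osbzip76-2 replicate 2. Reads in genes made up 83.0% to 86.0% of these totals. At the median gene length, 1 RPKM corresponded to 35.6 reads per library. On simulated tables the recovery gave the exact count for 99.0% of 5956 genes. Intervals given with read counts are exact 95% binomial intervals and cover counting error only.

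Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided) on log2(RPKM + 1). A gene was tested if its mean over the 6 libraries was at least 1 RPKM, which left 21454 genes. Fold changes from limma are on the log2(RPKM + 1) scale, which understates the change of low genes. Both alleles together were compared with WT in a 2-group fit of 3 libraries against 3. Each allele was compared with WT, and osbzip76-2 with osbzip76-1, in a 3-group fit that shares 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and the threshold was 0.05. The test was tried on simulated reads drawn for these genes and depths, with 200 genes changed. For both alleles against WT it recovered 41.8% of 2-fold and 81.6% of 4-fold changes, and 2 of its 123 calls were false, over 21419 genes. Reads were drawn for each gene independently, so no simulated library deviated as a whole, as WT replicate 2 did in the results below. These rates may thus not hold for the real libraries. A second count "adjusted over the list alone" uses the members of 1 gene list only.

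The table gives 35484 of its rows by RAP identifier only and 341 by a gene symbol or another name. The gene table used for names (assembly ASM3414082v1, a build other than IRGSP-1.0, so no row was matched by coordinates) matched 208 of the named rows and 1 of the others. Further names came from 61 pairs of identifier and symbol that were written from memory before the data were examined. Of these identifiers 52 were in the table, and the other 9 genes were there under their symbols. For 26 pairs the gene table held 1 gene of that symbol, in each case on the chromosome that the identifier names, and the remaining pairs have no such check. The pairs for 2 symbols, GLUC and GLB1, were left out because the gene table gives those symbols to other genes. Both had passed the chromosome check, which can thus miss a wrong pair. Among the pairs kept, start positions in the gene table followed the order of the identifiers in all 44 comparisons within a chromosome. In all, 200 named genes were tested. No source used here pairs a row of the table with OsbZIP76, and its transcript level was not analysed here.

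Before the data were examined, 20 gene lists were fixed. Named members were found for 11: starch synthesis, storage proteins, sucrose and sugar transport, NF-Y subunits, MADS-box genes, bZIP genes, Polycomb PRC2, DNA replication, auxin, nucellus, aleurone and embryo markers, and defence and stress response. The 9 lists of cell cycle, histone, cytokinesis and phragmoplast, cellulose and callose synthesis, cell wall remodelling, gibberellin, cytokinin and abscisic acid, photosynthesis, heat shock and ribosomal protein genes had no named members here and gave no result. Lists with at least 3 tested members, 6 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. The 4 further lists (chitinases, monosaccharide transporters, DOF transcription factors and organelle-encoded genes) were chosen after the data were seen and appear only among the additional observations. The rule for named genes was also fixed before the data were examined. It took every NF-YB gene of the NF-Y list, then named genes past the threshold for which the libraries of the compared groups did not overlap. These were up to 12 per direction for both alleles together and 5 per direction for each other comparison. From each list it took up to 4 members past the threshold or, with none, the 2 of highest mean RPKM. Further genes named from a list were chosen after their values were seen.

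Alternatives covered pseudocounts of 0.1 and 0.5, no filter on low values, a minimum mean of 5 RPKM, median-ratio rescaling, quantile normalization, limma without the trend, with robust estimation or with array weights, the replicate number as a block, a 2-fold minimum, a 3-group fit for both alleles together, an estimated correlation in camera, fry, and leaving out each library in turn. Limma's voom on the recovered reads and the estimated correlation without WT replicate 2 were added after the data were seen. Median-ratio factors of the libraries lay between -0.042 and 0.067 on the log2 scale. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.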

Results

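The series asked how the loss of OsbZIP76, a basic leucine zipper transcription factor tied to endosperm cellularization, changes the transcriptome of the young rice caryopsis. The caryopsis is the rice grain with its maternal pericarp, and its endosperm passes from a syncytium to a cellular tissue in the first days after fertilization. At the sampled stage, 2 days after fertilization, the hot season had already brought cellularization forward in both WT and mutant grains, according to the series description. RPKM values of 3 WT libraries, 2 osbzip76-1 libraries and 1 osbzip76-2 library were analysed. Between 16951685 and 21170107 reads per library lay in genes, and 26910 to 29012 genes per library had at least 1 read. Transcripts of OsbZIP76 itself were not analysed here, so the genotype labels have no check from the mutated gene.

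One WT library stood apart from all the others. WT replicate 2 had a score of -61.3 on the first principal component, which held 45.3% of the variance, while the other 5 libraries lay between -2.97 and 30.5. Its transcripts of BT1 (Os02g0202400), the ADP-glucose transporter of the amyloplast, stood at 12.3 RPKM against 110.8 and 114.6 RPKM in WT replicates 1 and 3. SUS3 (Os07g0616800), a sucrose synthase, stood at 35.8 against 147 and 138 RPKM, and NF-YB9 (Os06g0285200) at 3.56 against 15.1 and 17.2 RPKM. In contrast MADS29 (Os02g0170300), a MADS-box factor of maternal seed tissue, was at 140 RPKM in that library against 98.4 and 110 RPKM. The Polycomb gene FIE1 (Os08g0137100), expressed in endosperm, was at 77.1 against 61.8 and 59.7 RPKM. BT1 and SUS3 were chosen after their values were seen. The scatter of reads between WT replicates 1 and 3 gave a chi-square of 9.74 per degree of freedom, and the value was 44.2 and 43.9 when WT replicate 2 was set against them; for the osbzip76-1 pair it was 9.32.

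**Figure D1:**
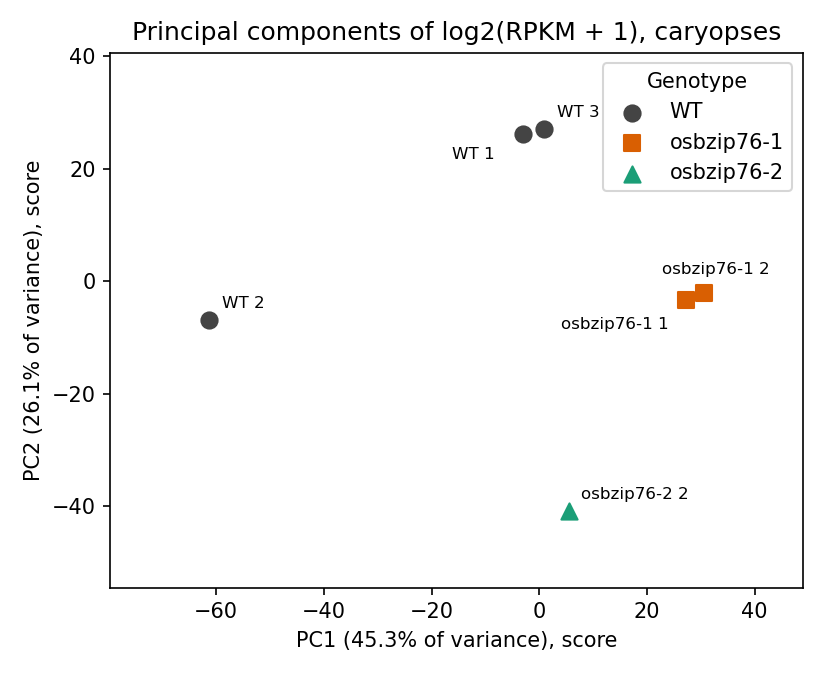
Scores of the 6 libraries on the first and second principal components of log2(RPKM + 1), with the share of variance on each axis and 1 point per library. WT replicate 2 lies at -61.3 on the first component, and osbzip76-2 replicate 2 lies lowest on the second, at -40.9.

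The main comparison set both alleles together against WT and asked which transcripts changed in grains without a normal OsbZIP76 gene. In this comparison 83 genes passed the threshold, 64 higher and 19 lower in the mutants, and 74 of them differed at least 2-fold. Of the 200 named genes tested 2 were among them, both higher, beside 83 of all 21454 genes tested. Cht7, a chitinase gene, stood at 2.88 ± 0.58 RPKM in the mutants against 0.230 ± 0.199 RPKM in WT (SD, n = 3 each), from 244 and 22 reads in all (limma log2 fold change 1.66, SE 0.21, adjusted p = 0.0297). DMAS1, which encodes an enzyme of mugineic acid synthesis for iron uptake, stood at 23.4 ± 2.9 against 9.44 ± 2.10 RPKM (limma log2 fold change 1.24, SE 0.18, adjusted p = 0.0432). Each was higher in 3 of 3 mutant libraries than in all WT libraries, which the rule for named genes required. The groups did not overlap for any of the 83 genes, so this adds no further support. No named gene was lower past the threshold, and 52 named genes had an unadjusted limma p under 0.05. Both calls remained without WT replicate 2, with limma adjusted p of 0.0296 and 0.0238, and were lost when any other single library was left out, with adjusted p from 0.0587 to 0.211; voom on the recovered reads gave 0.128 for Cht7 and 0.0614 for DMAS1.

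The genes that changed most in this comparison carry no name in the sources used here. Os03g0115800 had 97.4 ± 11.6 RPKM in the mutants and 0.0193 ± 0.0335 RPKM in WT (SD, n = 3 each). It was represented by 9075 reads in the mutants and 2 in WT, a depth-corrected ratio of 5017 with an exact 95% interval from 1388 to 41432. Os10g0569800 had 52.6 ± 14.6 against 0.0738 ± 0.0714 RPKM, from 1940 and 3 reads, a ratio of 715 with an interval from 244 to 3470. In the other direction Os09g0427300 fell from 67.7 ± 6.8 RPKM in WT to 2.24 ± 1.91 RPKM (limma log2 fold change -4.57, SE 0.36, adjusted p = 0.00221). Os10g0498300 fell from 34.7 ± 3.9 to 1.21 ± 1.047 RPKM (limma log2 fold change -4.11, SE 0.30, adjusted p = 0.00144). An unadjusted limma p under 0.05 was reached by 2945 genes, where 1072.7 were expected by chance, and these were split more evenly than the 83, with 1426 higher and 1519 lower. Without WT replicate 2 the count was 108, of which 70 were shared with the 83. It was 35 without WT replicate 1, 39 without WT replicate 3, 40 without osbzip76-1 replicate 1 and 34 without osbzip76-1 replicate 2, and voom gave 42. With array weights it was 1246 (712 higher and 534 lower). The weights were 0.22 for WT replicate 2, 3.76 for WT replicate 1 and 0.97 for WT replicate 3. The 1246 thus cannot be laid to the low weight of WT replicate 2 alone.

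Genes of starch synthesis stood higher in the mutants as a group. Of 25 members, 19 had a positive log2 fold change, with a median of 0.27, and the list passed camera (adjusted p = 5.44e-05). That call was lost with an estimated correlation between genes, where the adjusted p was 0.552. None of the 25 passed limma's threshold over all genes tested, 11 had an unadjusted p under 0.05, and 7 passed when adjusted over the list alone, all of them higher. These 7 were chosen after their values were seen, apart from BEIIb. GBSSI (Os06g0133000), the granule-bound synthase that makes amylose in the endosperm, stood at 48.7 ± 37.6 RPKM in the mutants and 6.52 ± 3.97 RPKM in WT (SD, n = 3 each; limma log2 fold change 2.64, SE 0.61, adjusted p = 0.0141 when adjusted over the list alone). AGPL2, a large subunit of ADP-glucose pyrophosphorylase, stood at 184 ± 15 against 69.0 ± 27.1 RPKM, and AGPS2, a small subunit, at 84.1 ± 2.0 against 41.7 ± 10.7 RPKM. BEIIb (Os02g0528200), an endosperm branching enzyme, stood at 229 ± 20 against 97.1 ± 41.3 RPKM, with a limma log2 fold change of 1.34 (SE 0.33). The other members that passed over the list alone were AGPS1, BEI (Os06g0726400) and PHO1 (Os03g0758100), at 1.68, 1.52 and 1.26 times their WT means.

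The other members of the starch list did not pass when adjusted over the list alone. AGPL3, the most abundant member, stood at 353 ± 31 RPKM in the mutants and 373 ± 35 RPKM in WT, a difference within the spread (limma log2 fold change -0.08, SE 0.13, adjusted p = 0.824). GBSSII (Os07g0412100), the granule-bound synthase of pericarp and leaf, chosen after its values were seen, had a log2 fold change of -0.32 (SE 0.14) and did not pass the threshold (limma adjusted p = 0.378). WT replicate 2 was below both other WT libraries in 20 of the 25 genes. Without it the list's median was 0.20, camera gave an adjusted p of 2.32e-05, or 0.143 with an estimated correlation, and 4 members passed limma over all genes tested: AGPL2, AGPS2, BEIIb and BT1. BT1 then had a log2 fold change of 0.98 (limma adjusted p = 0.0280), against 2.01 (adjusted p = 0.312) with all libraries.

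**Figure D2:**
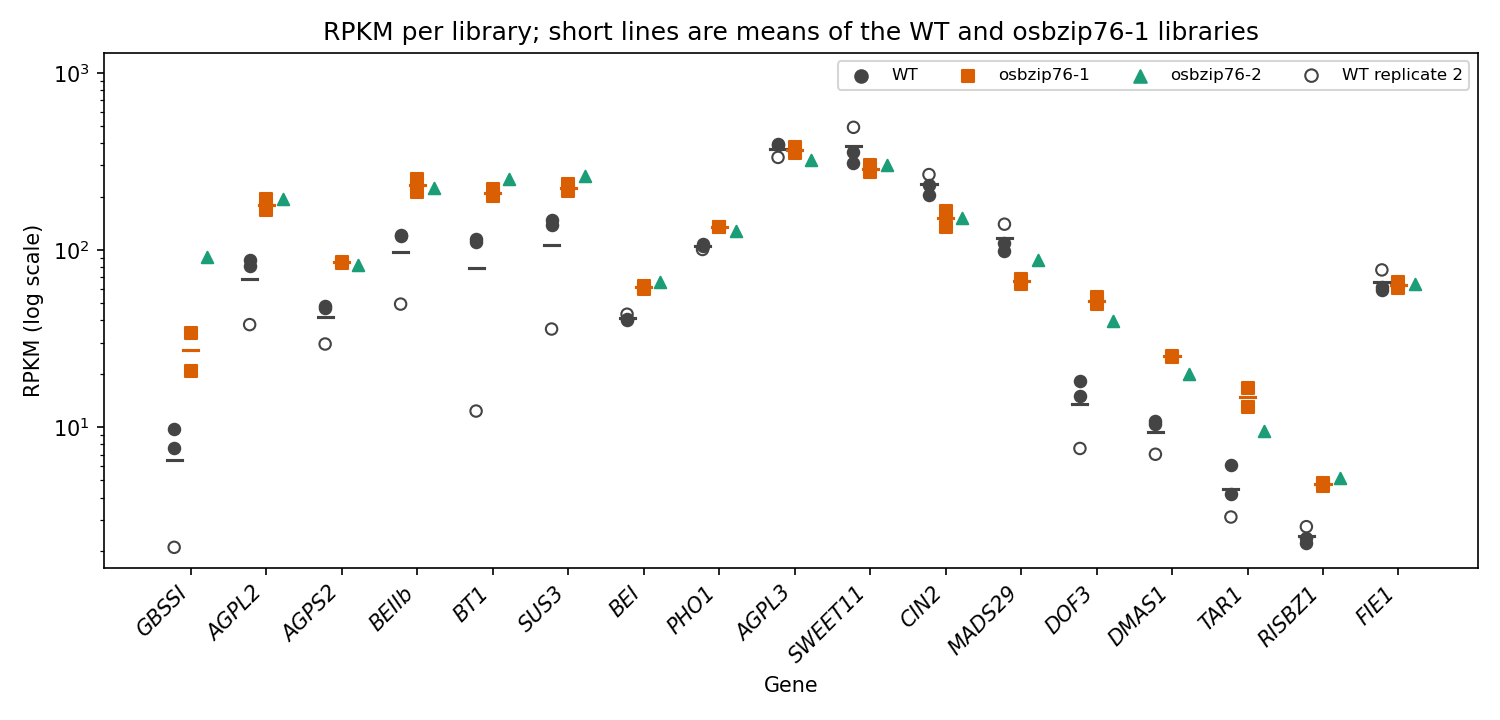
RPKM of 17 named genes on a log axis, 1 point per library (circles, WT, with WT replicate 2 open; squares, osbzip76-1; triangles, osbzip76-2), with short lines at the means of WT and osbzip76-1. All mutant libraries lie above all WT libraries for GBSSI, AGPL2, AGPS2 and BEIIb, and the groups overlap for AGPL3 and FIE1.

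Genes of sucrose and sugar transport did not pass as a group, and the members that passed over the list alone went in both directions. None of the 10 members of the sucrose and sugar transport list passed over all genes tested, 5 had an unadjusted limma p under 0.05, and 3 passed when adjusted over the list alone. CIN2 (Os04g0413500), a cell wall invertase that feeds the filling grain, was lower, at 151 ± 15 RPKM in the mutants against 234 ± 31 RPKM in WT (SD, n = 3 each; limma log2 fold change -0.63, SE 0.14, adjusted p = 0.0244 when adjusted over the list alone). SUS4 (Os03g0340500), a sucrose synthase, and SWEET14 (Os11g0508600), a sugar exporter, were higher, at 1.35 and 1.66 times the WT mean, and were chosen after their values were seen. SWEET11 (Os08g0535200), the most abundant member, stood at 292 ± 14 against 387 ± 95 RPKM and did not pass (limma log2 fold change -0.38, SE 0.18, adjusted p = 0.411); WT replicate 2 had 492 RPKM. SUS3 stood at 237 ± 23 against 107 ± 62 RPKM, with a limma adjusted p of 0.291, or 0.0691 without WT replicate 2. As a group the list did not pass camera (adjusted p = 0.260).

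Storage protein transcripts were at a low level and did not separate the mutants together from WT. With both alleles together, none of 6 tested members, all glutelin genes, passed the threshold or reached an unadjusted limma p under 0.05. The list did not pass camera (adjusted p = 0.525). Its median log2 fold change was -0.32 in osbzip76-1 and 1.58 in the 1 osbzip76-2 library. GLUA1 (Os01g0762500) had 3.58, 3.70 and 0.639 RPKM in WT replicates 1 to 3, 2.58 and 0.377 RPKM in the osbzip76-1 replicates and 16.4 RPKM in the osbzip76-2 library. GLUA2 (Os10g0400200) had 4.28 to 7.39 RPKM in WT, 6.61 and 3.68 RPKM in osbzip76-1 and 16.8 RPKM in osbzip76-2. Reads of these similar genes can be shared among them. Without osbzip76-1 replicate 2 the list passed camera at the preset correlation, with an adjusted p of 0.00153. With all libraries the estimated correlation between its genes was 0.973, and camera with it gave an adjusted p of 0.789.

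NF-YB proteins are named as OsbZIP76 partners in the series title. The NF-YB genes that could be named here, NF-YB1 and NF-YB9, did not pass the threshold. Any other NF-YB genes among the rows without a name were not identified. NF-YB1 (Os02g0725900) stood at 13.3 ± 8.2 RPKM in the mutants and 5.08 ± 2.39 RPKM in WT (SD, n = 3 each; limma log2 fold change 1.16, SE 0.45, adjusted p = 0.321). Its mutant libraries ranged from 6.42 to 22.4 RPKM and overlapped WT. NF-YB9 stood at 15.8 ± 2.8 against 11.96 ± 7.35 RPKM (limma log2 fold change 0.60, SE 0.48, adjusted p = 0.620), and without WT replicate 2 its log2 fold change was -0.039. Neither passed when adjusted over the list alone. The remaining member, NF-YC12, lay below the expression filter, so the list was too short for camera in the main analysis. In settings where all 3 members were tested it passed camera, higher in the mutants, with no filter (adjusted p = 0.0224), without WT replicate 1 (adjusted p = 0.0130) and without WT replicate 3 (adjusted p = 0.0427). It did not pass without WT replicate 2 (camera adjusted p = 0.121, or 0.574 with an estimated correlation).

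In the bZIP, MADS-box and auxin lists, 3 genes passed only when adjusted over their own list. RISBZ1, a bZIP activator of storage protein genes, stood at 4.90 ± 0.24 RPKM in the mutants and 2.44 ± 0.27 RPKM in WT (SD, n = 3 each; limma log2 fold change 0.78, SE 0.14, adjusted p = 0.0023 when adjusted over the list alone and 0.0791 over all genes), and was chosen after its values were seen. The more abundant bZIP genes RISBZ3 and RISBZ2 had log2 fold changes of -0.33 (SE 0.17) and -0.13 (SE 0.11). MADS29 was lower, at 73.5 ± 12.5 against 116 ± 21 RPKM (limma log2 fold change -0.65, SE 0.17, adjusted p = 0.0241 when adjusted over the list alone and 0.191 over all genes), while MADS58 stood at 103 ± 10 against 93.4 ± 6.7 RPKM. TAR1 (Os05g0169300), a tryptophan aminotransferase of auxin synthesis, stood at 13.03 ± 3.53 against 4.46 ± 1.51 RPKM (limma log2 fold change 1.37, SE 0.25, adjusted p = 0.0015 when adjusted over the list alone and 0.0882 over all genes). YUC9 (Os01g0273800), a later enzyme of that pathway, stood at 9.66 ± 1.11 against 10.8 ± 2.1 RPKM. TAR1 and YUC9 were the 2 tested members of the auxin list, so adjusting over that list alone changes a p-value little. The 4 bZIP and 4 MADS-box genes tested did not pass camera as lists (adjusted p = 0.638 and 0.778). The MADS-box list had a median log2 fold change of 0.01 and a mean of -0.11, of opposite sign.

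Polycomb genes did not pass the threshold. All 6 PRC2 genes tested had a limma adjusted p above the threshold, none had an unadjusted p under 0.05, and camera gave an adjusted p of 0.638. Os08g0137100 (named FIE1 here) stood at 63.8 ± 2.3 RPKM in the mutants and 66.2 ± 9.5 RPKM in WT (SD, n = 3 each). Os08g0137250 (named FIE2 here) stood at 38.3 ± 11.5 against 35.6 ± 10.8 RPKM. Neither name had a check against the gene table. PCNA (Os02g0805200), the sliding clamp of DNA replication and the 1 tested member of its list, stood at 74.0 ± 4.0 against 60.5 ± 8.5 RPKM (limma log2 fold change 0.29, SE 0.13, adjusted p = 0.364; unadjusted p = 0.0497). Of the markers of nucellus, aleurone and embryo, the embryo gene OSH1 stood at 5.61 ± 1.77 against 5.00 ± 1.73 RPKM, and the other tested marker was MADS29, for which WT replicate 2 had the highest level of the 6 libraries. Of the 2 tested defence genes Cht7 passed, and WRKY71 did not (limma adjusted p = 0.692).

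Each allele was also set against WT alone. In osbzip76-1 the count past the threshold was 82, with 57 genes higher and 25 lower. The osbzip76-2 library gave 148 genes, 133 higher and 15 lower. At an unadjusted limma p under 0.05 the balance turned for osbzip76-1, with 1269 genes higher and 1719 lower, and for osbzip76-2 it was 1154 higher and 360 lower. None of the 200 named genes was among either set. These sets were so small a share of the 21454 genes tested that few named genes would be expected in them. Of the named genes, 40 and 38 had an unadjusted limma p under 0.05. The starch list had a median log2 fold change of 0.36 in osbzip76-1 and 0.17 in osbzip76-2. GBSSI stood at 34.0 and 20.8 RPKM in the osbzip76-1 replicates and at 91.4 RPKM in osbzip76-2. Os09g0427300 stood at 1.16 ± 0.57 RPKM in osbzip76-1 (SD, n = 2) and at 4.40 RPKM in osbzip76-2. Without WT replicate 2 the counts were 525 (301 higher and 224 lower) and 529 (450 higher and 79 lower), and leaving out WT replicate 1, WT replicate 3 or either osbzip76-1 library gave 17 to 38 genes for osbzip76-1 and 36 to 55 for osbzip76-2. With a pseudocount of 0.1 the osbzip76-2 count was 29, without a filter on low values it was 282, and voom gave 38 genes for osbzip76-1 and 171 for osbzip76-2.

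The overlap of the alleles was 38 genes that changed in the same direction in both, 29 higher and 9 lower. Independent lists of these lengths would share 0.353 higher and 0.0175 lower genes, and at most 1 gene was shared in 100 simulations of unchanged groups set against the same WT libraries. Across genes, which are not independent replicates, the log2 fold changes of the alleles had a Pearson correlation of 0.522, against 0.314 in the simulations, and a covariance of 0.0904 against 0.02003. They had the same sign in 67.8% of genes, against 60.2% in the simulations. With 3 WT libraries the controls could not be split into parts of at least 2, so part of the excess may come from the shared controls. Os03g0115800, Os10g0569800, Os09g0427300 and Os10g0498300 were all among the 38. The overlap was 175 genes without WT replicate 2, 19 without WT replicate 1, 25 without WT replicate 3, and 13 and 12 without osbzip76-1 replicates 1 and 2.

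**Figure D3:**
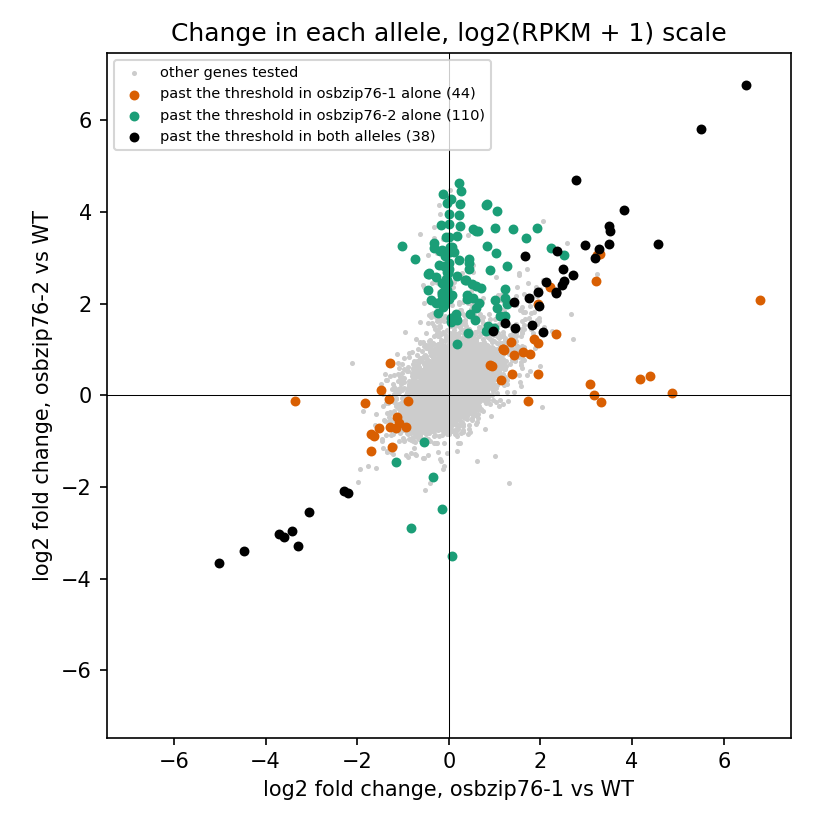
Limma log2 fold changes of 21454 genes on the log2(RPKM + 1) scale, osbzip76-1 against WT on the horizontal axis and osbzip76-2 against WT on the vertical axis, 1 point per gene. Black points mark the 38 genes past the threshold in both alleles, and colours mark the 44 and 110 genes past it in osbzip76-1 alone and in osbzip76-2 alone, which is not a test of a difference between the alleles.

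The direct comparison set the osbzip76-2 library against the osbzip76-1 libraries, and a difference between the alleles cannot be told here from the deviation of that 1 library. Here 46 genes passed the threshold, 39 higher and 7 lower in osbzip76-2, and 1055 genes had an unadjusted limma p under 0.05 where 1072.7 were expected by chance. None of the 46 was a named gene. GBSSI, with 91.4 RPKM against a mean of 27.4 RPKM in osbzip76-1, did not pass this comparison, and neither did GLUA1 with 16.4 against 1.48 RPKM. Quantile normalization gave 26 genes, 19 higher and 7 lower, and no filter on low values gave 179, 169 higher and 10 lower. The excess of higher genes was absent with a pseudocount of 0.1 (0 higher and 2 lower), at a mean of at least 5 RPKM (4 and 4) and without WT replicate 1 (3 and 5). The count rested on 1 osbzip76-2 library and was 8 without WT replicate 1, 264 without WT replicate 2, 15 without WT replicate 3 and 0 without either osbzip76-1 library (limma, with 621 and 782 genes at an unadjusted p under 0.05); voom also gave 0, with 993 genes at an unadjusted p under 0.05.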

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

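The tests of sequencing depth in WT replicate 2, of its place relative to the mutant change and of chromosomal neighbours against random sets were chosen after the results were seen. The starch list without that library and under other scalings was a planned run, but its use as a test of an explanation was chosen after the results were seen. No group had the 4 libraries that the search for outlying samples requires.

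In the direct test of osbzip76-2 against osbzip76-1, 46 genes passed the threshold, none of them named. This rests on 1 osbzip76-2 library, so a difference between the alleles cannot be told from the deviation of that library. An unadjusted limma p under 0.05 was reached by 1055 genes where 1072.7 were expected by chance, and the count was 0 with voom or without either osbzip76-1 library.

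WT replicate 2 stood apart from all other libraries. Across the 21454 genes, 1141 differed at least 2-fold on the log2(RPKM + 1) scale between it and the mean of the other WT libraries, 855 of them lower, against 72 between WT replicates 1 and 3. A lower number of reads alone is excluded as the cause, since 2 libraries had fewer reads in genes and did not stand apart. WT replicate 2 still had the fewest genes detected, 26910, against 27560 in osbzip76-1 replicate 1, which had fewer reads. It also had the lowest share of reads in genes, 83.0%, and the most genes without reads, 24.9%. Gene length was excluded as well. The Spearman rho of the change with length was -0.0712 over 21452 genes, closer to 0 than the -0.179 between WT replicates 1 and 3. A place on the axis of the mutant change was tested across all genes with a separate WT library as reference on each side: the mean rho was 0.0424, where that explanation needs a negative value. Most genes did not pass the threshold between mutants and WT. A rho over all genes can therefore miss an axis carried by the changed genes, and the test cannot exclude it. In this library the starch list had a median change of -0.58, the sucrose and sugar transport list -0.09 and the storage protein list 0.90. With WT replicate 2 left out, the medians of these lists in the mutants were 0.20, 0.16 and 0.68. The sign was thus opposite for starch and sugar transport and the same for storage proteins. In WT replicate 2, MADS29 and Os08g0137100 (named FIE1 here) were higher, and Os08g0137250 (named FIE2 here) was lower. Differences in tissue make-up, in library quality or in sampling stage were not settled by these values.

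Starch synthesis genes stood higher in the mutants. Without WT replicate 2 the list's median was 0.20 and 18 of its 25 members had a positive log2 fold change. The higher values thus did not come from that library alone, and camera at the preset correlation gave an adjusted p of 2.32e-05. Under median-ratio rescaling and quantile normalization the larger camera adjusted p was 0.000149. Camera sets a list against the other genes, so a factor that moves all genes of a library alike can hardly make or remove its call. The rescaled runs were therefore no test of such a factor. Median-ratio factors of the libraries lay between -0.042 and 0.067 on the log2 scale, against a list median of 0.27 with all libraries. These values argue against a common library factor as the source of the higher starch values. The call depends on camera's preset setting, since no camera test with an estimated correlation passed. The camera adjusted p was then 0.552 with all libraries, at an estimate of 0.255, and 0.143 without WT replicate 2. There the estimate was 0.0135, near the preset 0.01, so the size of the correlation can account for little of that loss. The other camera alternatives ranged from 1.51e-05 to 0.000446 in adjusted p. Fry, which tests the list against no change, gave an adjusted p of 0.272. A grain further along in filling at the same day, or a smaller share of maternal tissue in the caryopsis, was not tested and is not separated here from a direct effect of the gene; MADS29, of maternal tissue, had a log2 fold change of -0.65 and GBSSII, of pericarp, -0.32, and neither passed limma over all genes. Sampling time within the day after fertilization stays open in the same way.

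The genes changed in both alleles together against WT lay near each other on the chromosomes. Of 81 such genes with a RAP identifier, 25 had another within 10 tested genes by the order of their identifiers, against a mean of 5.84 and a 95th percentile of 12 in 10000 random sets (permutation p = 0.0001, the smallest they can give). Linked genome segments that differ between the lines, as from different seed stocks, may give such a pattern. Neighbours moving together in any comparison may give part of it, because sets of the same size that differed most between libraries of 1 genotype held up to 17 genes with a neighbour; these cannot be told apart, since 17 lies well above the random sets and below the 25 found. The direct effect of OsbZIP76 on clustered genes was not tested.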

How the results depend on the processing

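Voom and the estimated correlation without WT replicate 2 were chosen after seeing the data. Both alleles against WT gave 83 genes, and 137 with the 3-group fit, 52 with no filter on low values, 48 at a mean of at least 5 RPKM, 32 with the replicate block, 1246 with array weights, 42 with voom and 34 to 108 with 1 library left out. The replicate number does not pair the libraries (correlation of deviations -0.068 over 2 pairs), and with it as a block osbzip76-2 gave 78 genes in place of 148. Only 45 of the 52 genes without the filter and 69 of the 137 were among the 83. For osbzip76-1 the count of 82 became 38 with no filter, 49 at 5 RPKM, 38 with voom and 17 to 525 with 1 library left out. For osbzip76-2 the 148 became 29 and 80 with pseudocounts of 0.1 and 0.5, 282 with no filter, 41 at 5 RPKM and 36 to 529 with 1 library left out. The 46 genes that differed between alleles became 2 and 14 with those pseudocounts, 179 with no filter, 8 at 5 RPKM, 26 with quantile normalization, 75 without the trend, 0 with voom and 0 to 264 with 1 library left out. The 38 genes changed in both alleles became 23 with a pseudocount of 0.1, 23 with no filter, 23 at 5 RPKM, 25 with voom and 12 to 175 with 1 library left out. The causes of these moves were not tested. Leaving out osbzip76-2 replicate 2 gave no value for the comparisons of that allele.

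Of the fixed lists 1 passed camera, 3 with no filter, where NF-Y and defence genes reached 3 members, 0 with an estimated correlation, 0 with fry and 1 to 2 with 1 library left out (NF-Y genes also passed without WT replicates 1 or 3, storage proteins without osbzip76-1 replicate 2), or 0 without WT replicate 2 at an estimated correlation. The starch list kept its call in the other 16 settings (adjusted p from 1.51e-05 to 0.000446). Directions turned, with no list past the threshold, for storage proteins with the block (adjusted p = 0.910), array weights (0.980), without WT replicate 3 and without osbzip76-2 replicate 2, for bZIP genes with the block (0.910) and for MADS-box genes without WT replicate 2 (0.932, and 0.937 with an estimated correlation). With 1 library left out the adjusted p ranged from 0.00153, without osbzip76-1 replicate 2, to 0.901 for storage proteins and from 0.559 to 0.932 for MADS-box genes.

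Cht7 and DMAS1 kept their direction in all of the 33 settings run for the pair and passed in 15. The 4 unnamed genes passed in all 68. Of 624 settings of 37 other named genes, 588 kept direction and side of the threshold, 20 newly passed and 16 turned sign in genes that did not pass. Log2 fold changes that turned were 0.030 for YUC9 and -0.12 for GLUA1 with the block, and 0.030 for FIE1, -0.073 for FIE2, -0.13 for GLUA2 and -0.33 for GLUA1 with array weights. With 1 library left out they ranged from -0.11 to 0.071 for FIE1, -0.15 to 0.37 for FIE2, -0.12 to 0.32 for OSH1, -0.039 to 0.96 for NF-YB9, -0.26 to 0.71 for GLUA2 and -0.56 to 1.27 for GLUA1. The cause was not tested. Depth limits low genes most: Cht7 rests on 22 WT reads in all.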

Other observations

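The lists and genes of this part were chosen after the data were seen, as was the test of other splits.

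DOF transcription factors are a plant zinc finger family that includes regulators of seed storage genes. The members that passed when adjusted over this list alone went in both directions. DOF3 stood at 47.6 ± 7.3 RPKM in the mutants and 13.6 ± 5.4 RPKM in WT, and DOF5 at 18.9 ± 2.1 against 8.93 ± 1.77 RPKM (SD, n = 3 each). DOF2 was lower, at 19.9 ± 1.7 against 32.1 ± 10.1 RPKM, with 43.7 RPKM in WT replicate 2. These 3 passed limma when adjusted over the list alone, and none of the 4 over all genes tested; DOF3 passed there without WT replicate 2 (adjusted p = 0.0124). The list passed camera (adjusted p = 0.0402), and the adjusted p was 0.264 with an estimated correlation and 0.0192 to 0.287 over all camera alternatives; fry, which tests the list against no change, gave 0.0114.

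Log2 fold changes were positive for 7 of 8 chitinase genes tested, with a median of 0.94 and a camera adjusted p of 0.0017. It became 0.307 with an estimated correlation and ranged from 1.33e-07 to 0.580 over all camera alternatives, and fry gave 0.173. They differed strongly between libraries of 1 genotype: their summed RPKM was 48.3, 42.3 and 91.4 in WT replicates 1 to 3, 43.0 and 95.3 in osbzip76-1 replicates 1 and 2, and 120.4 in osbzip76-2. Cht9 stood at 13.3 RPKM in osbzip76-2 and at 0.442 to 2.64 RPKM in the other libraries. Of the monosaccharide transporters MST4 and MST6, the former passed when adjusted over the list alone, with a log2 fold change of 0.87 (SE 0.27).

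Organelle-encoded transcripts, of which 10 were tested, had a camera adjusted p of 0.0546, or 0.498 with an estimated correlation and 9.74e-05 to 0.913 over all camera alternatives, and fry gave 0.497. Their summed RPKM was 20.1, 45.7 and 17.5 in WT replicates 1 to 3, 34.3 and 22.0 in osbzip76-1 and 55.5 in osbzip76-2. The summed RPKM of the glutelin genes was 16.1, 19.9 and 5.80 in WT, 15.6 and 4.72 in osbzip76-1 and 53.9 in osbzip76-2. It was likewise highest in osbzip76-2 and next in WT replicate 2, with another order below.

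In 10 genes every library of 1 genotype class had at least 5 RPKM and every library of the other at most 0.5 RPKM, 6 expressed in the mutants and 4 in WT. None of the 9 other splits of the libraries into 3 and 3 gave such a gene. All 10 were among the 83 genes past the threshold in both alleles together against WT, and none has a name here. A further 2 genes met these bounds for osbzip76-1 alone and 9 for osbzip76-2 alone. Of the 10, 4 lie on chromosome 11, and 4 had another of the 10 within 10 tested genes.

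The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 83 genes and was the 1 split that gave as many, and the highest of the other splits gave 0.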
